A study of Homo sapiens and Mus musculus with 53 samples.

How the data were processed

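RNA was measured in sorted keratinocytes of adult mouse dorsal epidermis and in primary human keratinocytes grown in serum-free medium, transduced with lentiviral shRNA against Mi-2β or a control and selected in puromycin, per the labels' protocols. These protocols name shRNA for Mi-2β and control only; how JUN was targeted is not given in the sources used here. Mouse RNA libraries were made with a stranded kit, but whether strand was used in counting is not given, so overlapping and antisense genes could not be told apart. Mouse genes of families with near-identical copies (Serpinb3 and Stfa genes) and human ones (the SPRR2 family, FAM25C and FAM25G) are uncertain, as are IGF2 and VIM, which overlap INS-IGF2 and VIM-AS1.

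The submitters' processing notes name bcl2fastq 1.8.3, Bowtie2, STAR, HOMER, DESeq2 and MACS2 with the builds hg19 and mm10. The deposited RNA values are a signal: reads per gene counted over exons with HOMER and then scaled by the authors to equal library totals with its simple normalization, per the file headers. The table of human genes held 25541 genes and that of mouse genes 24537; 27 human and 26 mouse names that a spreadsheet had turned into dates were restored from their identifiers. Normalized totals were 39821357 to 39929874 in human and about 5581774 in mouse libraries. Because each value is a whole number of reads times a factor per library, the reads were recovered: of values up to 20 reads, 100% came out whole in every library within 0.1 read. In the first Mi2KD library of experiment 2 the step lies too near 1 for the general unit check, and it was tested separately, with 100% whole. Recovered depth was 22067442 to 45577650 reads in 17 human and 4664390 to 8059684 in 6 mouse libraries, with 18031 to 19650 and 14307 to 15149 genes having a read. The 10 largest genes took 8.54 to 15.57% of human and 5.94 to 7.82% of mouse reads. A value cannot resolve less than 1 read, so genes near 0 are imprecise. The file held 1 column of per-sample values that was not used, because its name matched no label; the comparison at 96 h was therefore not analysed here.

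ATAC-seq regions were called with MACS 2.1.1.20160309 on 2 pooled libraries per group against pooled libraries of the other group, per the file headers, with reads shifted and extended (shift 37, extension 73) and duplicates kept. ATAC-seq libraries were made with a transposase kit. The files give fold enrichment, a ratio computed by the authors, and −log10 q values, also deposited by the authors. Human ChIP-seq lists were called with HOMER, 1 list per factor and condition except 2 for Mi-2β in CTR, per the file headers. Their controls were inputs, except that the HaCaT list of Mi-2β had a control named for H3K27ac in HaCaT. Inputs differed between CTR and Mi2KD. Mi-2β list 1 came from combined libraries. The score of each peak is the authors' own and was used only to describe peaks within a list. A mouse Mi-2β ChIP-seq library and its input were not used here.

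The design assumed raw counts; because the deposited values are normalized, the tests planned for such values were used. Genes with a mean of at least 10 were tested with limma 3.58.1 (trend) on log2(value + 1), all groups of an experiment in 1 fit, with Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(value + 1) scale and understate those of low genes. edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 on the recovered reads were alternatives, of which edgeR called 5953 genes at 6 h, 2751 at 24 h and 2800 between them, 5327 at day 3, 7775 at day 5, 4649 in Mi2KD, 1499 in JUNKD and 3124 in DKD. The computations used R 4.3.3, Python 3.11.15, pandas 2.3.3, SciPy 1.17.1, bedtools 2.31.1 and matplotlib 3.10.9. Gene lists were tested with camera at a preset correlation of 0.01 over 17 lists and 7 cell type lists, of which 22 were tested in mouse and 24 in human, with an estimated correlation beside it; fry, also run, tests whether a list moves and not whether it differs from other genes. The lists are the AP-1 family, inflammatory cytokines and chemokines, antimicrobial and alarmin, wound-edge keratins, proteases and EGFR ligands, NF-kB targets and feedback, immediate early and MAPK feedback, interferon response, cornified envelope and late differentiation, spinous layer, basal layer and hemidesmosome, cell cycle, p53 targets and cell cycle inhibitors, NuRD subunits, cholesterol synthesis and uptake, barrier lipid enzymes, mesenchymal transition, and unfolded protein and amino acid stress. The cell type lists are markers of fibroblasts, leukocytes, neutrophils, Langerhans cells, melanocytes, endothelial cells and hair follicle or sebaceous cells.

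Named genes were CHD4 and JUN, the 8 largest rises and 8 largest falls among called genes whose groups did not overlap and whose mean log2 CPM was at least 2, without unnamed models, and up to 4 members of each list with the smallest p. KLK5, TNC, BST2 and SPRR3, named for DKD against Mi2KD, came from the lists. Top2a and Cd34 at 24 h, FOSL1, HBEGF and ASNS at day 5, COL1A1 in Mi2KD of experiment 2 and CXCL14 between DKD and Mi2KD fall outside this rule and were named after their values were seen. This rule, the lists, the tests and most alternatives were fixed before the data were examined. Region overlaps needed at least 1 bp, and overlaps of genes were tested with Fisher's exact test. That test takes genes as independent units, which genes that move together are not, and does not measure the spread between libraries. ATAC-seq regions were assigned to all genes starting within 50 kb and to the nearest gene at any distance. ChIP-seq peaks were assigned to the nearest gene if it started within 50 kb. A floor of 3 counts per library was used for genes with no read in a group, and intervals and floors cover counting error only.

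Replicates are separate libraries of a group by the labels, which do not say whether they came from separate animals or cultures, so p-values measure the spread between libraries, which may be technical. Replicates of each group differed by more than sampling noise. Replicate numbers were checked as pairs by the correlation of deviations from the group means. In experiment 2 they were 0.224, 0.457 and 0.596 between CTR and Mi2KD and 0.524, 0.407 and 0.6 between CTR and JUNKD. Between libraries of different numbers the highest was 0.201 for CTR and Mi2KD and 0.07 for CTR and JUNKD. The numbers thus pair CTR with JUNKD, but CTR with Mi2KD only in part. This pairing comes from the data and not from the labels. Mi2KD and JUNKD gave 0.074 for replicate 1, so they were not taken as pairs. The other groups have 2 libraries each, and the labels' numbers of DKD did not pair with those of CTR, Mi2KD or JUNKD. The file header numbers the DKD libraries otherwise than the labels, and gives the second Mi2KD library of experiment 2 a group name that may mark another day. The analysis was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold: 58 and 97 were recovered at 6 h, 64 and 88 at 24 h, 44 and 95 at day 3, 32 and 91 at day 5, 28 and 94 in Mi2KD, and 34 and 91 in JUNKD. Shared controls were simulated, after the data were seen, with unchanged groups whose spread was that of the 3 CTR libraries. These groups were drawn independently, so the pairing of replicate numbers did not enter the simulated ranges. The alternatives covered the tool, scaling, filter, pseudocount, pairing, left-out libraries, set test, peak threshold and overlap.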

Results

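Barrier disruption was modelled in adult mouse skin by tape stripping, which peels off the outer cornified layer. Keratinocytes of the dorsal epidermis were sorted as integrin alpha-6-positive cells that lacked CD45, a leukocyte marker, and CD34, a marker of hair follicle bulge cells. RNA was sequenced from unstripped wild-type (WT) skin and from skin collected 6 h and 24 h after stripping, with 2 libraries per group. Open chromatin was profiled by ATAC-seq, a transposase assay, in the same 3 conditions and in Chd4-/- epidermis, with 2 libraries per group pooled by the authors. Chd4 encodes Mi-2β, the ATPase of the NuRD chromatin remodelling complex. In primary human keratinocytes, Mi-2β was depleted with lentiviral shRNA. Experiment 1 held control (CTR) cells and cells at day 3 and day 5 of Mi-2β knockdown (Mi2KD), with 2 libraries per group. Experiment 2 held CTR, Mi2KD and JUNKD cells with 3 libraries per group and DKD cells with 2; the last 2 names are those of the labels. The file header puts the second Mi2KD library of experiment 2 under another group name than the other two, which may mark a different day of knockdown, so means and SDs of that group may mix days. ChIP-seq peak lists covered Mi-2β, the AP-1 subunits cJUN and JUNB, 2 histone marks and RNA polymerase II. The recovered depth was 4664390 to 8059684 reads per mouse RNA library and 22067442 to 45577650 per human RNA library.

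To follow the early response to barrier disruption, keratinocytes at 6 h were compared with WT. Wound-edge genes rose in 18 of 18 cases, antimicrobial and alarmin genes in 6 of 8 and cornified envelope genes in 10 of 17, and cell cycle genes fell in 17 of 28. These lists passed with the preset correlation, and had adjusted p values of 0.451 to 0.744 with an estimated correlation. Krt6a, a keratin of wounded epidermis (chromosome 15, 101689928 to 101694305, mm10), rose from 70.0 ± 0.83 to 15264 ± 2215 normalized reads (mean ± SD, n = 2 in each mouse RNA group; log2 change 7.74, limma adjusted p = 6.46e-08). F3, which encodes tissue factor, and Procr, the protein C receptor, rose by 9.59 and 9.22 on the log2 scale. The stromelysin gene Mmp10 rose by 8.25. The collagenase gene Mmp13 and the cytokine gene Il24 had no read in WT and were at least 222-fold and 123-fold higher at 6 h, taking 3 counts per library as the floor.

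Of the 18 wound-edge keratins, proteases and EGFR ligands tested, 18 rose at 6 h, with a median log2 change of 5.72 (camera adjusted p = 5.56e-16; adjusted p = 0.451 with an estimated correlation). They included the EGFR ligands Hbegf (25.8 ± 6.02 to 1185 ± 119) and Tgfa (107 ± 4.05 to 2160.1 ± 173). Among 8 AP-1 family genes 3 rose and 2 fell, and the list did not pass (adjusted p = 0.171). Fosl1, an AP-1 subunit (chromosome 19, 5447698 to 5455938), rose from 21.7 ± 1.43 to 1632 ± 168, and Junb rose by 1.31 on the log2 scale. Jun was 388 ± 174 in WT and 408 ± 24.7 at 6 h (adjusted p = 0.71). Among 8 antimicrobial and alarmin genes 6 rose and 1 fell (adjusted p = 0.00582; adjusted p = 0.534 with an estimated correlation). S100a9 and S100a8, the calprotectin subunits, rose by 7.07 and 5.64, and Lcn2, a siderophore-binding protein, by 2.65. Among 17 inflammatory cytokines and chemokines 7 rose and 4 fell, or 8 and 4 adjusted over the list alone (adjusted p = 0.0271; adjusted p = 0.636 with an estimated correlation). This call was lost with TMM scaling (adjusted p = 0.0974; 0.0291 to 0.636 over the alternatives run). The neutrophil chemoattractant Cxcl1 rose by 5.27, whereas the interferon-induced chemokine Cxcl10 fell by 3.72 on the log2 scale.

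Differentiation and lipid genes also moved at 6 h. Of 17 cornified envelope genes 10 rose and 2 fell (adjusted p = 0.000345; adjusted p = 0.59 with an estimated correlation). The envelope precursor Sprr1b rose by 8.09, and Tgm1, the transglutaminase that cross-links the envelope, rose from 10.5 ± 1.29 to 364 ± 19.6. Barrier lipid enzymes rose in 10 of 15 genes and fell in 2, or rose in 10 and fell in 3 adjusted over the list alone (adjusted p = 0.000345; adjusted p = 0.57 with an estimated correlation). In the basal layer list 8 of 17 genes rose and 4 fell (adjusted p = 0.116). The basal keratin Krt15 fell by 2.71 on the log2 scale. Of 28 cell cycle genes 1 rose and 17 fell, or 1 and 18 adjusted over the list alone (median -0.66, adjusted p = 0.00839; adjusted p = 0.744 with an estimated correlation). The proliferation marker Mki67 (chromosome 7, 135689788 to 135716379) fell by 1.45 and the DNA topoisomerase gene Top2a fell by 1.05 on the log2 scale. Chd4 (chromosome 6, 125095981 to 125130591) was 2637 ± 63.1 in WT and 1869 ± 62.1 at 6 h (log2 change -0.50, adjusted p = 0.0112). That call was lost with TMM scaling (adjusted p = 0.103), with DESeq2 (0.0675), with edgeR (0.12) and without the second 6 h library, and the adjusted p ran from 0.00469 to 0.12 over the alternatives. Chd3, a paralog of Chd4, fell by 1.96 on the log2 scale. In all, 2310 of 11977 genes were higher and 3792 lower, and TMM scaling, which differed from the deposited scaling by -0.1976 (log2) between these groups, gave 3079 and 2917. Without the second 6 h library 3800 genes were called.

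**Figure D1:**
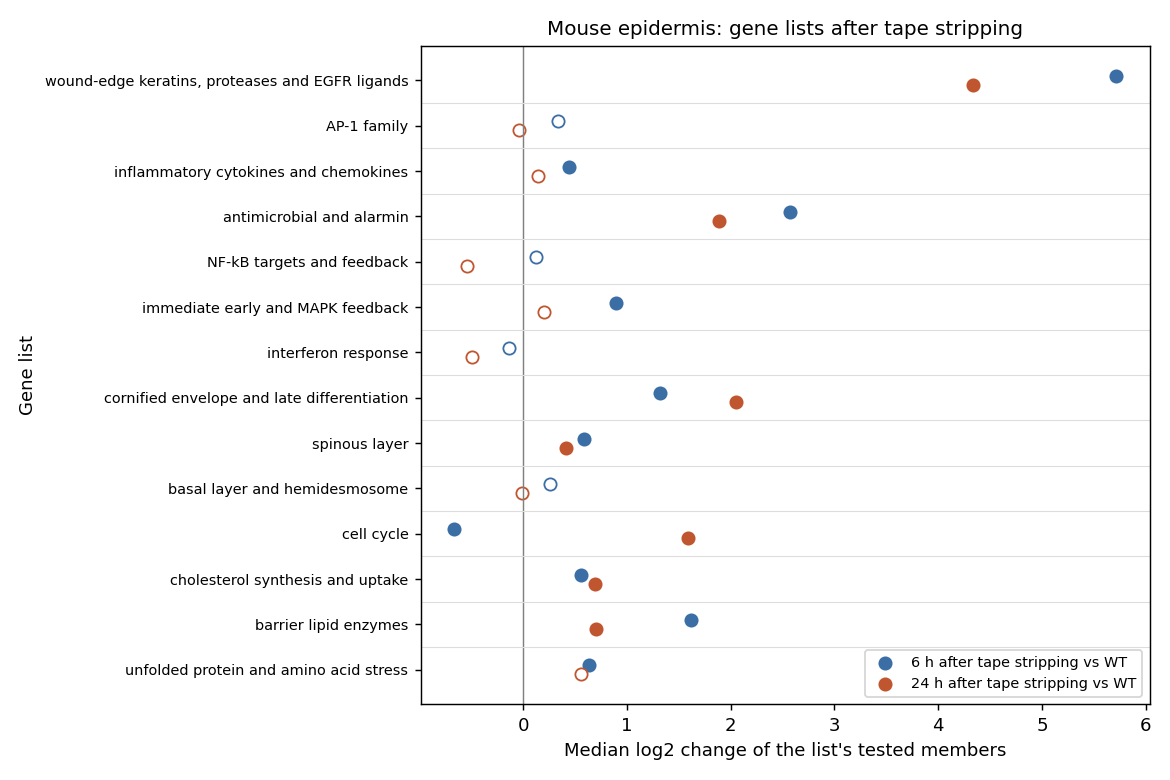
Median log2 change of gene lists, for 6 h against WT and 24 h against WT. The p53, NuRD and mesenchymal transition lists and the cell type lists are not drawn. Filled circles mark camera adjusted p under 0.05 with the preset correlation and open circles the others. The cell cycle list lies at -0.66 at 6 h and at 1.59 at 24 h, and the wound-edge list at 5.72 and 4.34.

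To ask which of these changes lasted, 24 h was compared with WT. The wound keratins and the AP-1 subunit Fosl1 were higher than in WT, and cell cycle genes rose in 27 of 28 cases (adjusted p = 0.391 with an estimated correlation). Krt6a was 14397 ± 2324 (log2 change 7.65, limma adjusted p = 1.29e-07), and Krt6b, its paralog in wounded epidermis, rose by 7.38. Fosl1 rose by 2.46 and S100a9 by 7.01. Wound-edge genes rose in 17 of 18 cases (adjusted p = 2.49e-20; adjusted p = 0.33 with an estimated correlation). The cell cycle list had a median of 1.59 (adjusted p = 2.49e-20). Mki67 rose from 1446 ± 97.5 to 4273 ± 421 and Top2a reached 2925 ± 459. Cornified envelope genes rose in 10 of 17, or 12 adjusted over the list alone (adjusted p = 5.28e-10; adjusted p = 0.391 with an estimated correlation), among them Tgm1 (4.00) and Sprr1a (2.74). Cholesterol synthesis genes rose in 8 of 17, or 12 adjusted over the list alone (adjusted p = 4.48e-06; adjusted p = 0.415 with an estimated correlation), among them Sqle, the squalene epoxidase (1.68). Krt15 fell by 1.68 on the log2 scale, a call lost without the second 24 h library. Chd4 was 2901 ± 256 (0.14, adjusted p = 0.46) and Jun 384 ± 118 (0.03, adjusted p = 0.95). In all, 1484 genes were higher and 1017 lower. The total of 2501 became 421 without the second 24 h library and 1581 without the first WT library. A replicate block raised the total, although the pairing of the mouse libraries is not established.

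The direct comparison of 24 h with 6 h tested how the response moved with time. All 28 cell cycle genes were higher at 24 h (median 2.32, camera adjusted p = 1.68e-21; adjusted p = 0.757 with an estimated correlation), with Mki67 higher by 3.01 on the log2 scale (limma adjusted p = 5.94e-05). Wound-edge genes were higher in 2 cases and lower in 8, or 2 and 9 adjusted over the list alone (adjusted p = 0.000774; adjusted p = 0.757 with an estimated correlation). Mmp10 had a log2 change of -3.91 and Fosl1 of -3.71. NF-kB targets and feedback genes were lower in 6 of 16 (adjusted p = 0.00175; adjusted p = 0.757 with an estimated correlation). Nfkbia, the inhibitor that closes NF-kB signalling, was 1290.2 ± 68.6 at 6 h and 498 ± 59.5 at 24 h. Chd4 was higher at 24 h than at 6 h (0.63, adjusted p = 0.00986), a call lost without the second 6 h or the first 24 h library. In all, 1823 genes were higher and 908 lower, and TMM scaling gave 1573 and 1237. Leaving out single libraries left 855 (without the first 24 h library), 1024, 1640 or 1719 genes.

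Markers of other cell types were measured in the sorted mouse cells. Cd34, the marker used to exclude bulge cells, was 119.67 in the first and 12.43 in the second WT library, 12.26 and 4.75 in the 6 h libraries, and 53.08 and 15.24 in the 24 h libraries. The 6 h value did not pass by limma (adjusted p = 0.094) but passed with DESeq2 (adjusted p = 0.00942), edgeR (0.046 with TMM) and the replicate block (0.00411), over alternatives of 0.00411 to 0.571. Tyrp1, a melanocyte gene, was 120.86 and 12.43 in WT and 176.18 and 6.23 at 24 h. No melanocyte marker of 4 passed in either comparison with WT, and without the first WT and first 24 h libraries 4969 genes were called at 6 h, 2311 at 24 h and 2026 between them. That fit leaves 1 WT and 1 24 h library, which are assumed to vary like the 6 h pair. Cxcr2, the chemokine receptor of neutrophils and the only neutrophil marker tested, rose from 0.52 ± 0.74 to 149 ± 46.6 at 6 h and 104 ± 51.0 at 24 h. The hair follicle or sebaceous markers Scd1, Mgst1 and Lhx2 were called lower at 6 h (log2 changes -1.33, -1.33 and -2.68). So were the Langerhans cell markers H2-Eb1 (-1.18) and H2-Aa (-0.86), although neither list passed.

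To compare chromatin opening after injury with that after loss of Mi-2β, the authors' pooled ATAC-seq region lists were counted and overlapped. Far more regions were gained than lost in each condition, without a replicate check because libraries were pooled. Depth differed, with 22904101 tags in WT, 17059544 at 6 h, 17483747 at 24 h and 23957906 in Chd4-/- epidermis. Chd4-/- epidermis had 27059 regions over WT, covering 4369.3 kb with a median fold of 5.34, and 1941 in the reverse direction. Stripped skin had 9171 regions over WT at 6 h and 61 in reverse, and 6232 and 32 at 24 h. Of the 6 h regions 32.32% (95% Wilson interval 31.37 to 33.28) overlapped a Chd4-/- region by at least 1 bp, and of the 24 h regions 36.92% (35.73 to 38.13). In the other direction, 10.87% of the 27059 Chd4-/- regions overlapped a 6 h region and 8.4% a 24 h region. The overlap expected of unrelated lists was not computed. At 24 h 51.3% (50.06 to 52.54) of regions overlapped a 6 h region. All lists used the same WT libraries, so part of these overlaps may come from the shared controls. A stricter threshold of 10 on the deposited -log10 q scale left 7037, 1227 and 578 gained regions. A Chd4-/- region lay at the start of F3 (chromosome 3, 121723189 to 121723754, fold 10.4). Near Krt6a, regions lay at 101697556 to 101697630 at 6 h and at 101694400 to 101694528 at 24 h. Tgm1 had a Chd4-/- region (chromosome 14, 55713415 to 55713709) and a 6 h region (55715137 to 55715348).

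**Figure D2:**
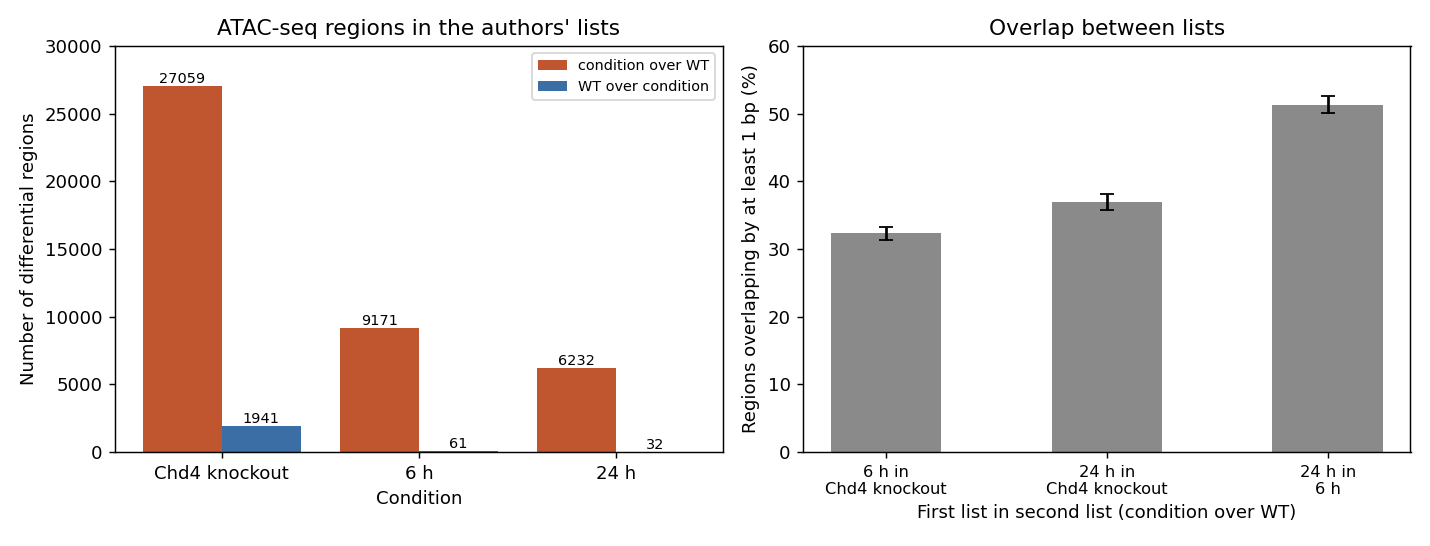
Left, number of ATAC-seq regions in each deposited list; right, percentage of the regions of a list that overlap another list, with 95% binomial intervals. The Chd4-/- list over WT is the longest, at 27059 regions, and 51.3% of 24 h regions overlap a 6 h region.

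Genes starting within 50 kb of a gained region, and the gene nearest to each region at any distance, were then set against the RNA calls in 11973 genes. The alternatives of 10 kb and 100 kb changed the window only and kept the nearest genes. Fisher's exact test took genes as independent units here. At 6 h 22.2% of the genes near such a region rose, against 17.4% of the others (odds ratio 1.35, Fisher's exact p = 1.15e-10, adjusted p = 7.47e-10). At 24 h the shares were 14.1% and 11.5% (odds ratio 1.27, exact p = 4.54e-05, adjusted p = 0.000148). Genes that fell had an odds ratio of 0.856 at 6 h (exact p = 0.000125, adjusted p = 0.000325), a call lost within 10 kb (0.955, exact p = 0.296, adjusted p = 0.308). At 24 h their odds ratio was 1.0 (exact p = 0.972), but 1.31 within 10 kb (exact p = 0.000416, adjusted p = 0.000901) and 0.877 within 100 kb (exact p = 0.0485, adjusted p = 0.063).

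In the human experiments the targeted genes were examined first, in every library. CHD4 (chromosome 12, 6679248 to 6716599, hg19) was 9842.9 and 9209.9 normalized reads in the CTR libraries of experiment 1, 2400.2 and 2252.4 at day 3, and 1522 and 1908.2 at day 5. In experiment 2 it was 8215, 11127.5 and 7360.7 in CTR, 2235.2, 3963.4 and 3038.2 in Mi2KD, and 3885.2 and 3782 in DKD. The libraries labelled JUNKD held 11175.5, 13142.4 and 14784.3. JUN (chromosome 1, 59246463 to 59249785), which encodes the AP-1 subunit cJUN, was 2971.6, 3579.2 and 3636.1 in CTR of experiment 2. It was 4768.6, 4766.7 and 3216.7 in the libraries labelled JUNKD, and 5594.7 and 3709.2 in DKD. JUN mRNA was thus not lower in the libraries that carry its name, which goes against that label, and every direction drawn from the JUNKD and DKD libraries carries this limit.

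**Figure D3:**
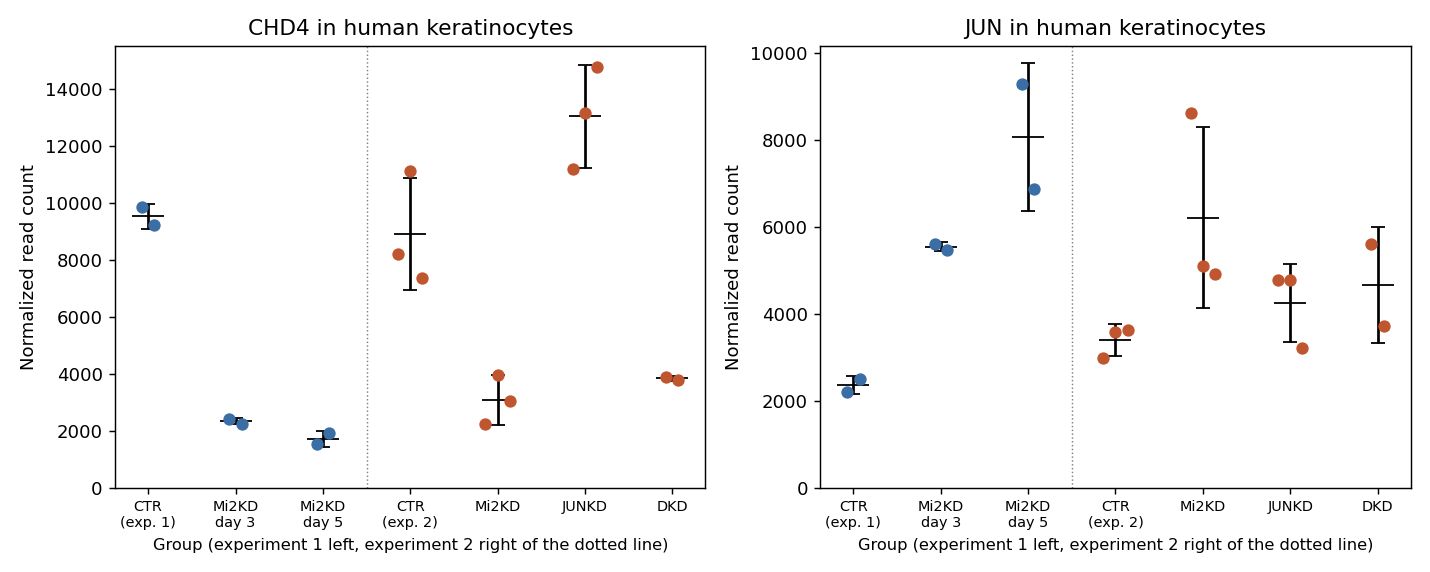
Normalized read counts of CHD4 and JUN in each human RNA library (dots), with the group mean (bar) and SD (error bar), in 7 groups. CHD4 lies between 1522 and 3963.4 in the Mi2KD libraries, and JUN between 3216.7 and 4768.6 in the libraries labelled JUNKD against 2971.6 to 3636.1 in CTR of experiment 2.

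To measure what loss of Mi-2β changed, day 3 of knockdown was compared with CTR in experiment 1. The labels give no day for these CTR libraries, so time in culture cannot be separated from the knockdown at either day. Interferon-response genes rose in 17 of 23, and cell cycle, unfolded protein and amino acid stress, and cholesterol genes fell in 19 of 28, 9 of 11 and 6 of 18. These 4 lists passed with the preset correlation, and each had an adjusted p = 0.872 with an estimated correlation. CHD4 was 9526 ± 448 in CTR and 2326 ± 105 at day 3 (n = 2 in each group of experiment 1; log2 change -2.03, limma adjusted p = 0.000539). JUN rose from 2352 ± 209 to 5544 ± 96.4 (1.24, adjusted p = 0.00285). The epithelial chemokine CXCL14 (chromosome 5, 134906371 to 134914969) rose from 399 ± 233 to 46483 ± 2.18 (6.99). The WNT ligand WNT10A rose by 6.15, PAMR1 by 5.18, the proteoglycan gene DCN by 4.99 and the receptor NOTCH4 by 4.69. PLAT, the tissue plasminogen activator, fell by 4.33 on the log2 scale, the gap junction gene GJB2 fell by 4.06 and the mitochondrial folate enzyme MTHFD2 fell by 3.68. The interferon list had a median of 1.62 and 20 genes higher adjusted over the list alone (adjusted p = 7e-07). BST2, an interferon-induced tether of budding virus, rose from 52.0 ± 3.04 to 1746 ± 977. Adjusted over the list alone, 24 cell cycle, 10 stress and 7 cholesterol genes fell (adjusted p of the lists = 4.22e-10, 7.1e-06 and 0.00362). Inflammatory genes rose in 2 of 28 and fell in 9, or 2 and 10 adjusted over the list alone (adjusted p = 0.0431; adjusted p = 0.872 with an estimated correlation), and TMM scaling ended that call (0.0663; 0.02 to 0.872 over the alternatives). Among them the alarmin cytokine IL1A fell from 18777 ± 1099.6 to 2206 ± 497, and the granulocyte growth factor CSF3 fell by 4.14 on the log2 scale. The cornified envelope list did not pass (adjusted p = 0.105), although SPRR2D, one of a family of near-identical genes whose reads may be split among them, fell by 4.01. The AP-1 subunit FOSL2 rose by 0.77. Among markers of other cell types, 3 of 3 leukocyte markers tested rose (CD74 by 1.5, CD68 by 1.30 and LAPTM5 by 2.30), as did 2 of 7 fibroblast markers (DCN and PDGFRA), although neither list passed (camera adjusted p = 0.0564 and 0.0813). The other leukocyte markers of the list, PTPRC, CD3E, TYROBP and FCER1G, were not tested. The neutrophil marker CXCR2 and the endothelial marker VWF rose by 2.06 each, and of 5 hair follicle and sebaceous markers KRT75 rose by 2.56 while SOX9 fell by 1.16 and SCD fell by 0.83; these lists did not pass either (adjusted p = 0.457, 0.61 and 0.695). The call for VWF was lost with DESeq2 (adjusted p = 0.111) and with edgeR (0.0686), among others (0.0404 to 0.21 over the alternatives). Without the first CTR library the calls for GJB2 (-4.54), IL1A (-3.17), CD74 (1.53), CD68 (1.08), VWF (2.64), SOX9 (-0.97) and SCD (-0.88) were lost. Without the second CTR library those for GJB2 (-3.59), IL1A (-3.05), CSF3 (-3.24), FOSL2 (0.67), CD74 (1.48), CXCR2 (1.45), VWF (1.48), SOX9 (-1.35) and SCD (-0.79) were lost. The calls for GJB2 (-2.85), CXCR2 (1.76), VWF (2.07), SOX9 (-0.77) and SCD (-0.84) were also lost without the first day 3 library, and those for CSF3 (-3.78), CD68 (0.98), LAPTM5 (2.25), VWF (2.05) and SCD (-0.83) without the second. In all, 2974 of 15723 genes were higher and 2339 lower. The total of 5313 became 2194 without the first CTR library, and at most 3078 without any other single library.

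At day 5 interferon genes rose in 16 of 23, and cell cycle, unfolded protein and amino acid stress, and cholesterol genes fell in 27 of 28, 7 of 11 and 10 of 18 against CTR. These 4 lists passed with the preset correlation, and each had an adjusted p = 0.925 with an estimated correlation. Both times share their CTR libraries and are not independent. CHD4 was 1715 ± 273 (log2 change -2.48, adjusted p = 0.000139) and JUN 8073 ± 1707 (1.77, adjusted p = 0.000383), by limma. CXCL14 reached 102577 ± 25500.5 (8.11), DCN rose by 6.94, WNT10A by 6.74 and NOTCH4 by 5.92. The growth regulator MYC fell from 13397 ± 182 to 2318 ± 1518, and the EGFR ligand HBEGF and the asparagine synthetase gene ASNS were also lower. FOSL1 fell by 2.1 on the log2 scale (adjusted p = 0.0428), a call lost with DESeq2 (0.129), with edgeR (0.0738), with no filter (0.0533) and without either CTR library or the second day 5 library (0.0027 to 0.153 over the alternatives). In the interferon list 16 genes rose and 1 fell adjusted over the list alone (adjusted p = 0.00205), and the cell cycle list had a median of -2.45 (adjusted p = 4.11e-12). Adjusted over the list alone, 8 stress and 12 cholesterol genes fell (adjusted p = 0.00184 for each list). Markers of other cell types also moved. LAPTM5 (2.87) and CD68 (1.02) rose, or 3 of 3 tested leukocyte markers adjusted over the list alone. CXCR2 (2.61), VWF (2.88), the melanocyte gene PMEL (0.99) and KRT75 (4.23) rose as well, while SCD fell by 1.74 and SOX9 fell by 2.04. Of 7 fibroblast markers DCN and PDGFRA (4.14) rose and COL3A1 fell by 1.67, or 2 rose and 2 fell adjusted over the list alone. None of these lists passed (adjusted p = 0.261 to 0.949). The calls for COL3A1 and PMEL were lost with edgeR (adjusted p = 0.0501 each) and without either CTR or the second day 5 library, and that for PMEL also without the first (0.00909 to 0.146 and 0.0258 to 0.159 over the alternatives). That for CD68 was lost without the first CTR or first day 5 library (adjusted p = 0.118 and 0.0628) and that for VWF without the second CTR library (0.0546). In all, 4305 genes were higher and 3467 lower. The total of 7772 became 4818 without the second CTR library and 4932 without the first.

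Between day 5 and day 3, 7 genes were higher and 23 lower by limma, with 2700 at an unadjusted p under 0.05. DESeq2 called 999 and edgeR 130, no gene was called in the fit of these 2 groups alone, and leaving out single libraries gave 0 to 487, the latter without the second day 5 library. A replicate block raised the count of 30 as well. Deviations of libraries with the same number correlated at 0.367, but 2 libraries per group do not establish pairs. Cell cycle genes had a median of -1.15 (camera adjusted p = 1.07e-13; adjusted p = 0.83 with an estimated correlation), with 0 lower over all genes and 20 lower adjusted over the list alone.

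Experiment 2 compared Mi2KD with CTR in other libraries. Interferon genes rose in 10 of 23, and unfolded protein and amino acid stress genes fell in 8 of 11, inflammatory genes in 11 of 26, NF-kB genes in 7 of 16 and cornified envelope genes in 12 of 33. Of these lists only that of stress genes passed with an estimated correlation (adjusted p = 0.0409); the others had adjusted p values of 0.577 to 0.687, and TMM scaling also ended the cornified envelope call. CHD4 was 8901 ± 1975 in CTR and 3079 ± 865 in Mi2KD (n = 3 each; log2 change -1.55, limma adjusted p = 0.00121). JUN was 3396 ± 368 and 6209 ± 2080.1 (0.83, adjusted p = 0.0328), a call lost without the first or second CTR or the first Mi2KD library. CXCL14 rose from 229 ± 149 to 36096 ± 15393 (7.39), NOTCH4 by 5.71 and DCN by 4.84. The hair follicle keratin KRT75 rose by 4.80, WNT10A by 4.19 and METTL7A by 4.16. SPRR2D, whose family caveat applies here too, fell by 4.63 on the log2 scale, the glycoprotein hormone gene STC2 fell by 4.34 and the stress pseudokinase gene TRIB3 fell by 3.63. In the interferon list 13 genes rose adjusted over the list alone (adjusted p = 4.75e-05). BST2 rose from 140.1 ± 24.9 to 1760.2 ± 524, RSAD2 by 2.48 and IFIT1 by 2.00. The stress list had a median of -1.49 (adjusted p = 4.06e-06).

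Inflammatory genes fell in 11 of 26 and rose in 1, or rose in 2 adjusted over the list alone (adjusted p = 0.00379), and NF-kB genes fell in 7 of 16 and rose in 1, or fell in 8 and rose in 1 adjusted over the list alone (adjusted p = 0.00365); both had an adjusted p = 0.577 with an estimated correlation. IL1A fell by 2.99 and its antagonist gene IL1RN fell by 2.08 on the log2 scale. TNFAIP3, which ends NF-kB signalling, fell by 1.17, and the antimicrobial ribonuclease RNASE7 rose by 1.62. Cornified envelope genes fell in 12 of 33 and rose in 4 (adjusted p = 0.0203; adjusted p = 0.687 with an estimated correlation), and TMM scaling ended that call (0.0645; 0.00669 to 0.687 over the alternatives). The transcription factor MAF rose by 1.88 and NOTCH3 by 1.65, whereas PRDM1 fell by 1.58. Wound-edge genes rose in 3 of 18 and fell in 4 (adjusted p = 0.549): HBEGF fell by 3.11 and the urokinase receptor PLAUR fell by 1.66, while MMP3 rose by 2.84 and the matrix gene TNC by 1.98. FOSL1 fell by 1.67, MYC fell by 1.74 and the MAPK phosphatase gene DUSP5 fell by 1.34. COL7A1, the anchoring fibril collagen, rose by 1.49, and ITGA3 fell by 1.17. Cell cycle genes fell in 3 of 28, or 0 adjusted over the list alone (adjusted p = 3.82e-05; adjusted p = 0.645 with an estimated correlation). Of 7 fibroblast markers 2 rose, DCN and PDGFRA, or 3 adjusted over the list alone, whereas COL1A1, the most abundant, was 12749 ± 8714 in CTR and 14748 ± 10575 in Mi2KD (adjusted p = 0.85). The leukocyte marker CD74 rose by 1.67, CXCR2 by 1.65, the endothelial marker KDR by 1.81 and the hair follicle marker LGR5 by 1.52, and SCD fell by 0.82; their lists did not pass (adjusted p = 0.251 to 0.703). The call for LGR5 was lost without the first CTR, the third CTR or the second Mi2KD library (adjusted p = 0.0512 to 0.0642). That for SCD was lost without the first or second CTR, the first Mi2KD or the third Mi2KD library (0.0899 to 0.184) and with only the compared groups (0.0999; 0.00595 to 0.184 over the alternatives). Without the 4 libraries lowest on the third principal component, KDR, LGR5 and SCD lost their calls (0.0522, 0.0541 and 0.0615; 0.00395 to 0.0522 and 0.0117 to 0.0642 over the alternatives for KDR and LGR5). In all, 2745 of 15864 genes were higher and 1872 lower. Fitting only the compared groups called 2484 genes, and without the first Mi2KD library 2491 were called. With the replicate number as a block and the DKD libraries, which share the fit, renumbered after the file header, 7803 were called.

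Both experiments measured the same knockdown, in separate libraries. Of 15376 genes tested in both, 2231 were higher in each (day 5 of experiment 1), against 729 expected of independent lists, and 1542 were lower in each, against 411. Discordant calls numbered 0 and 2. Across genes, which are not independent replicates, the log2 changes had a Pearson r of 0.854 and a Spearman rho of 0.841. With day 3 in place of day 5 these were 0.888 and 0.874.

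The libraries labelled JUNKD were compared with CTR to see which genes differed in the arm named for the AP-1 subunit. Wound-edge genes fell in 7 of 18 and unfolded protein and amino acid stress genes in 5 of 11, and both lists passed with an estimated correlation (adjusted p = 0.0219 each). JUN itself was 4251 ± 895 against 3396 ± 368 (n = 3 each; log2 change 0.31, limma adjusted p = 0.46), and CHD4 was 13034 ± 1807 (0.56, adjusted p = 0.126; 0.0251 with the replicate block and the DKD libraries renumbered after the file header, and 0.0251 to 0.499 over the alternatives). The interstitial collagenase gene MMP1 (chromosome 11, 102660641 to 102668966) fell from 959 ± 626 to 24.9 ± 35.4 (log2 change -5.99, adjusted p = 0.00566). The cytokine IL1B (chromosome 2, 113587337 to 113594356) fell by 2.74 on the log2 scale, the insulin-like growth factor binding protein gene IGFBP5 fell by 3.41 and STC2 fell by 2.74. IGF2, whose reads overlap the INS-IGF2 gene, rose by 3.32, DPYSL4 by 3.02 and the neurofilament gene NEFL by 2.74. Wound-edge genes fell in 7 of 18 and rose in 1, or 10 and 1 adjusted over the list alone (median -0.61), among them HBEGF and the EGFR ligand EREG. Unfolded protein and amino acid stress genes fell in 5 of 11, or 6 adjusted over the list alone (median -1.06), among them ASNS, TRIB3 and DDIT3. Each list had an adjusted p of 1.4e-07, and 0.0219 with an estimated correlation.

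Other lists in the libraries labelled JUNKD were lower only with the preset correlation. Inflammatory genes fell in 5 of 26 and rose in 2, or 6 and 2 adjusted over the list alone (adjusted p = 3.39e-05), and basal layer genes fell in 3 of 17 (adjusted p = 2.73e-05); each had an adjusted p = 0.278 with an estimated correlation. Melanocyte markers had a median of -1.28 (adjusted p = 0.00544; adjusted p = 0.457 with an estimated correlation), with 0 of 6 lower over all genes and 2 adjusted over the list alone. HLA-DRA, the 1 Langerhans cell marker tested, fell by 2.67, whereas the fibroblast marker PDGFRA (1 of 7) and the endothelial marker KDR rose by 2.43 each and LGR5 by 1.71. The Langerhans cell, fibroblast and endothelial lists did not pass (adjusted p = 0.0819, 0.937 and 0.103). The call for HLA-DRA was lost without any single CTR library, the first JUNKD or the third JUNKD library (adjusted p = 0.0518 to 0.0826) and with only these groups fitted (0.0945; 0.000281 to 0.1 over the alternatives). That for PDGFRA was lost without any single JUNKD library (0.0596 to 0.068), that for KDR without the third JUNKD library (0.0545), and that for LGR5 without the first CTR, the third CTR, the first JUNKD or the third JUNKD library (0.0622 to 0.0952). LGR5 also lost it with DESeq2 (adjusted p = 0.0709; 0.0119 to 0.14 over the alternatives). KRT15 fell by 1.78, ITGA3 fell by 1.40 and ITGB4 fell by 1.13. The kallikrein KLK5, which sheds cornified cells, fell by 1.49, MYC fell by 1.64 and FOSL1 fell by 1.12. CDKN1A, the p21 inhibitor, rose by 1.28, a call lost with TMM scaling (adjusted p = 0.0573) and with edgeR (0.0714), among others (0.00356 to 0.0908 over the alternatives). In all, 1409 genes were higher and 502 lower. TMM scaling, which differed from the deposited scaling by 0.1795 (log2), gave 698 and 764. With the replicate number as a block, 2884 were higher and 1008 lower, or 5316 in all with the DKD libraries renumbered after the file header. The total of 1911 became 171 without the third JUNKD library, 295 without the second, 1255 without the first and 824 without the first CTR library. It was 803 with only these groups fitted and 0 by limma without the 4 libraries lowest on the third principal component (the third CTR, Mi2KD and JUNKD libraries and the second DKD library). Of the 23 named genes called, 17 lost their call without the third JUNKD library, 10 without the second and 8 without the first CTR library.

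DKD was compared with CTR and with Mi2KD. All arms of experiment 2 are set against the same 3 CTR libraries, so part of any likeness between their changes may come from these controls. Against CTR, CHD4 was 3834 ± 73 (n = 2; log2 change -1.19, limma adjusted p = 0.00967) and JUN 4652 ± 1333 (0.43, adjusted p = 0.317). CXCL14 rose to 7556 ± 2498 (5.19), DCN by 4.86 and KRT75 by 2.94, and ASNS fell by 3.71 on the log2 scale. Unfolded protein and amino acid stress genes fell in 9 of 11 (median -1.88, camera adjusted p = 4.62e-08; adjusted p = 0.0185 with an estimated correlation), and inflammatory genes in 7 of 26 (adjusted p = 0.000193; adjusted p = 0.425 with an estimated correlation). The stress genes varied widely in CTR, where ASNS was 10186 ± 6110 (n = 3). With unchanged groups that vary like the CTR libraries, the stress list's median lay between -1 and 1.05 in Mi2KD, -0.95 and 0.99 in the libraries labelled JUNKD and -1.11 and 1.17 in DKD in 95% of 1000 simulated draws. The simulated medians of Mi2KD correlated at 0.451 with those of DKD and at 0.479 with those of the libraries labelled JUNKD through the shared controls. Cornified envelope genes rose in 6 of 33, although the list did not pass (median 0.90, adjusted p = 0.6). FLG, the filaggrin gene, rose from 1237 ± 629 to 3900 ± 932, the epithelial transcription factor OVOL1 by 1.96 (edgeR adjusted p = 0.0657; 0.00143 to 0.18 over the alternatives) and the lipid transporter ABCA12 by 1.72. Markers of other cell types moved here too. CD74 rose by 1.74, CXCR2 by 2.08, KDR by 3.70 and LGR5 by 2.35, PDGFRA rose by 3.47 beside DCN (2 of 7 fibroblast markers, with 1 fallen adjusted over the list alone), and SCD fell by 1.34 and SOX9 fell by 1.46. Their lists did not pass (adjusted p = 0.114 to 0.896). CHD4, FLG and SOX9 lost their calls without either DKD library, PDGFRA, SCD and OVOL1 without the second, SOX9 and OVOL1 without the first CTR library and OVOL1 without the second (adjusted p = 0.0505 to 0.18 for these). Without the 4 libraries lowest on the third principal component PDGFRA, LGR5, SCD and SOX9 lost their calls (0.0947, 0.103, 0.108 and 0.0547; at most 0.0947, 0.103, 0.144 and 0.123 and at least 0.000224, 0.00363, 2.66e-05 and 2.66e-05 over the alternatives). In all, 2246 genes were higher and 1027 lower, and TMM scaling, which differed by 0.1403 (log2), gave 1674 and 1450. The total of 3273 became 395 without the second DKD library, 1328 without the first and 2021 without the first CTR library, 1277 in the fit of these 2 groups alone, 6434 with the replicate block and the DKD libraries renumbered, and 454 without the 4 libraries lowest on the third principal component.

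**Figure D4:**
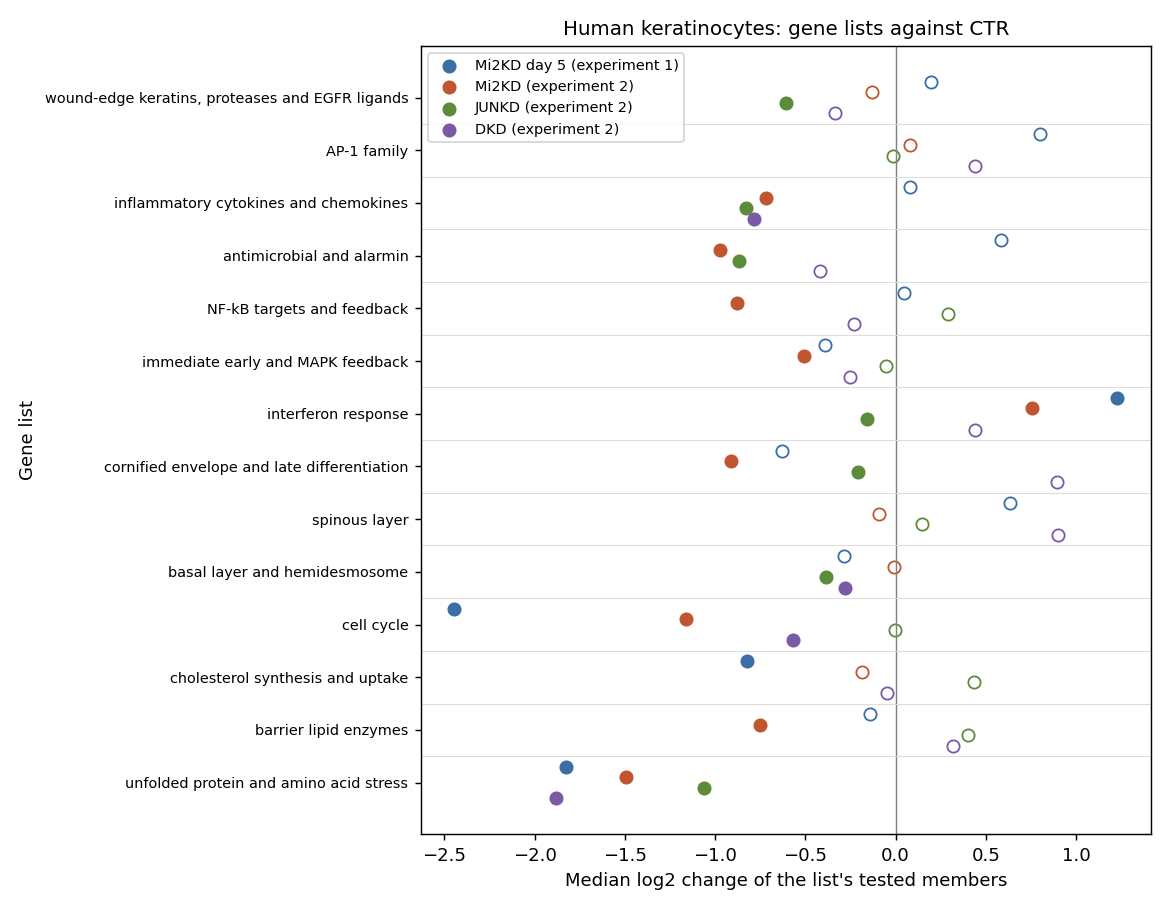
Median log2 change of gene lists in Mi2KD at day 5 of experiment 1, and in Mi2KD, the libraries labelled JUNKD and DKD of experiment 2. Each is set against its CTR. The p53, NuRD and mesenchymal transition lists and the cell type lists are not drawn. Filled circles mark camera adjusted p under 0.05 with the preset correlation and open circles the others. The unfolded protein and amino acid stress list lies at -1.83, -1.49, -1.06 and -1.88; the last 3 values share their CTR libraries and are not independent.

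Between DKD and Mi2KD, 6 genes were higher in DKD and 11 lower by limma, with 2290 at an unadjusted p under 0.05. DESeq2 called 555 and edgeR 15, and leaving out single libraries gave 0 to 4. A replicate block with the DKD libraries renumbered after the file header called 589. The block with the labels' numbers, which did not pair DKD with the other groups, called still more. CHD4 (0.36, adjusted p = 0.583) and JUN (-0.40, adjusted p = 0.59) did not pass. DPYSL4 (chromosome 10, 134000414 to 134019280) was 103 ± 29.2 in Mi2KD and 730.4 ± 73.5 in DKD (log2 change 2.85, adjusted p = 0.0153). GRHL1, an epidermal transcription factor, was higher by 2.18, the carbonic anhydrase CA2 by 2.04, SCEL, a cornified envelope precursor, by 1.88 and ZNF512B by 1.5. Among the lower genes, GPNMB had a log2 change of -2.49, OST4 -2.30, the fringe gene LFNG -2.02, ANXA3 -1.79, EMC7 -1.72, PFN2 -1.33, LSM1 -1.21 and DKK3 -1.05. All 13 of these genes lost their call without the first DKD library (adjusted p = 0.186 to 0.189), the second (0.285 to 0.61), the first Mi2KD library (0.0536 to 0.153) or the third (0.0512 to 0.0882), and 11 without the second. GRHL1 and ANXA3 also lost it with edgeR (adjusted p = 0.0523 each), and CA2 and DKK3 with TMM scaling (0.0545 and 0.0509).

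The fixed lists gave a wider difference between DKD and Mi2KD with the preset correlation. Cornified envelope genes had a median of 1.96 (camera adjusted p = 1.19e-07; adjusted p = 0.319 with an estimated correlation), with 12 of 33 higher and 1 lower adjusted over the list alone and 0 over all genes. Interferon genes had a median of -0.48 (adjusted p = 1.26e-06; adjusted p = 0.272 with an estimated correlation), with 2 of 23 lower adjusted over the list alone and 0 over all genes. CXCL14 (-2.20), KLK5 (-1.55), TNC (-1.77), BST2 (-1.67) and SPRR3 (4.22) did not pass by limma (adjusted p = 0.0869, 0.0533, 0.0564, 0.0708 and 0.0681). They passed with DESeq2 (0.000327, 5.59e-06, 3.68e-05, 0.000131 and 0.00777), and reached 0.582 to 0.72 at most over the alternatives.

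Gene sets chosen in experiment 1 were then read in experiment 2, whose libraries are separate. The 2688 tested genes of the risen set had a median log2 change of 1.03 in Mi2KD, 0.43 in the libraries labelled JUNKD, 0.89 in DKD and -0.15 between DKD and Mi2KD, against -0.03, 0.14, 0.02 and 0.08 in the other genes. The 2151 genes of the fallen set had medians of -0.88, -0.06, -0.63 and 0.27, against 0.23, 0.22, 0.26 and 0.01. With an estimated correlation both sets passed in Mi2KD (adjusted p = 0.0266 each) and in DKD (0.0435 each), and neither in the libraries labelled JUNKD (0.298 each). For the last comparison camera gave p = 1.05e-08 and 4.39e-09, and neither call held with an estimated correlation (p = 0.216 and 0.259). The 3 arms share the 3 CTR libraries. With unchanged groups simulated against them the median of the risen set lay between -0.19 and 0.19 in DKD in 95% of 1000 draws, and that of the fallen set between -0.28 and 0.28. In the libraries labelled JUNKD the risen set's range was -0.16 to 0.16, which its observed median of 0.43 exceeded. The fallen set's range there was -0.24 to 0.24, which holds its observed median. The interaction of the 4 groups, which asks whether DKD differs from the sum of the other changes, called 0 genes by limma (1299 at an unadjusted p under 0.05), 0 by edgeR and 61 by DESeq2. Unfolded protein and amino acid stress genes passed in it (median 0.88, camera adjusted p = 4.92e-07; adjusted p = 0.0337 with an estimated correlation), with 5 of 11 adjusted over the list alone. CTR, where these genes varied widely, enters the interaction too, and its part in this result was not simulated.

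ChIP-seq peak lists placed Mi-2β and AP-1 on the human genome, with 1 list per factor and condition except 2 for Mi-2β in CTR, so differences between conditions have no replicate check. Mi-2β peaks numbered 12820 in list 1 and 23815 in list 2, and 4986 of list 1 (38.89%) overlapped list 2. Of these shared peaks 75.53% overlapped H3K27ac, a mark of active regulatory regions, 39.61% H3K4me3, a promoter mark, and 13.68% JUNB. H3K27ac peaks numbered 46364 in CTR and 58722 in Mi2KD, and 54.76% of the latter overlapped the former. The H3K27ac libraries also differed in depth and in the estimated share of tags in peaks, with 17510997 tags and 19.17% in CTR and 22935236 tags and 25.44% in Mi2KD, per the file headers. cJUN peaks numbered 89 in CTR and 14335 in Mi2KD, with an estimated share of tags in peaks of 0.02% and 0.89% per the file headers. Of the Mi2KD cJUN peaks 27.4% overlapped JUNB and 4.35% a shared Mi-2β peak. At JUN, Mi-2β peaks lay just upstream at 59250456 to 59251777 (list 1) and 59250351 to 59251825 (list 2), and a cJUN peak of Mi2KD lay over the gene start at 59249721 to 59249879. At MMP1 a cJUN peak of Mi2KD lay at 102668905 to 102669063.

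For each list, only the region with the highest score at CXCL14 was read. In CTR these regions lay at the start of the gene. In Mi2KD those of RNA polymerase II and H3K27ac spanned it. Whether further CTR regions lay over the gene was not examined. The RNA polymerase II region covered 134914248 to 134914748 in CTR and 134904418 to 134916493 in Mi2KD. That of H3K27ac covered 134913957 to 134914792 in CTR and 134904126 to 134916465 in Mi2KD. That of H3K4me3 covered 134914314 to 134915151 in CTR and 134910903 to 134915626 in Mi2KD. The Mi2KD libraries were deeper for each, with 35561351 against 22844249 tags for RNA polymerase II (32.69% and 31.09% in peaks) and 10989810 against 8670848 for H3K4me3 (39.61% and 41.51%).

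**Figure D5:**
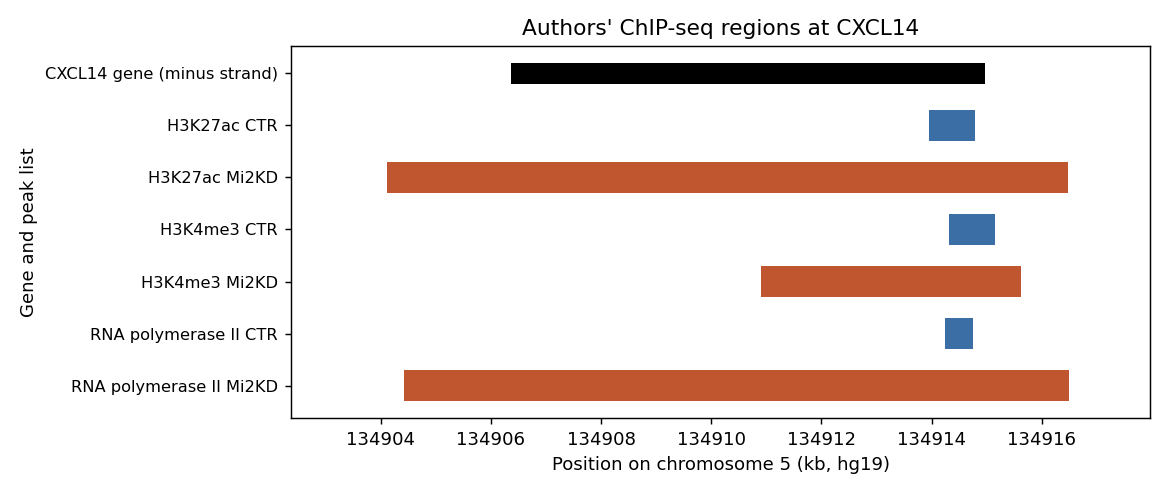
Map of the highest-scoring H3K27ac, H3K4me3 and RNA polymerase II region of each list at CXCL14 on chromosome 5 (hg19). CTR is blue and Mi2KD orange, and the gene is on the minus strand. Other regions of these lists are not drawn. The polymerase region runs from 134914248 to 134914748 in CTR and from 134904418 to 134916493 in Mi2KD.

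Genes near Mi-2β peaks were compared with the Mi2KD calls of experiment 2 in 15722 genes, of which 3810 lay near a peak in both lists. Of the bound genes 15.3% fell, against 10.7% of the others (odds ratio 1.5, Fisher's exact p = 1.74e-13, adjusted p = 1.51e-12). The shares that rose were 18.6% and 16.7% (odds ratio 1.14, exact p = 0.00716, adjusted p = 0.0116). These shares were not compared within bins of expression, so expression level may be part of both differences. The exact test again took genes as independent units. With the list from HaCaT, an immortalized keratinocyte line, the odds ratio for rising turned to 0.9 (exact p = 0.0884) and that for falling was 1.08 (exact p = 0.249). The control of that list was a library named for H3K27ac in HaCaT, not an input, per the file header.

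To set the knockdown against the injury response, human and mouse genes with the same symbol were compared, 10113 genes in all. Genes lower in Mi2KD and higher at 6 h numbered 503, against 289 expected of independent lists (odds ratio 2.53, Fisher's exact p = 5.22e-47, adjusted p = 1.25e-46). Genes higher in Mi2KD and lower at 6 h numbered 675, against 480 (odds ratio 1.92). Same-direction overlaps were below expectation, with 196 higher in both against 321 (odds ratio 0.508) and 301 lower in both against 431 (odds ratio 0.574). At 24 h, 349 genes were lower in Mi2KD and higher in the mouse, against 186 (odds ratio 2.57). HBEGF and FOSL1 were lower in Mi2KD, and their mouse counterparts Hbegf and Fosl1 were higher at 6 h. The 6 h and 24 h comparisons share their WT libraries and are not independent. Fisher's exact test takes genes as independent units, which genes that move together are not. Its p-values therefore do not measure the spread between libraries.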

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

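The test of expression level was chosen before its result was seen, and the tests of scaling, wrong labels, cell cycle genes, library number, replicate kinds and other splits only after.

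Effects differed between times: 2731 genes differed between 24 h and 6 h after stripping and 30 between day 5 and day 3 of Mi2KD, by limma. The Mi2KD effect at day 5 of experiment 1 differed from that of experiment 2 in 8 of 24 gene lists by camera with the preset correlation. It differed in 0 lists with an estimated correlation, and in 0 of 15902 genes by limma (1347 at an unadjusted p under 0.05). The labels give no day for experiment 2, so the day of knockdown cannot be separated from the experiment here. The cell cycle list differed by -1.395 in its median, and the spinous list by 1.1865 (day 5 of experiment 1 minus experiment 2). In the interaction of experiment 2, the risen and fallen sets of experiment 1 had camera p values of 5.17e-30 and 1.08e-33; with an estimated correlation the adjusted p values were 0.0608 and 0.0648.

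JUN mRNA was not lower in the libraries labelled JUNKD, with a mean of 4251 against 3396 in CTR. After TMM scaling, which differed from the deposited scaling by 0.1795 (log2), the change of JUN was 0.1268. This value follows from that shift, so it argues only against the choice between these 2 scalings as the cause. Whether control libraries stand under a wrong label is not settled. The wound-edge and stress lists passed by camera at an adjusted p of 0.0219 with an estimated correlation. Yet with the CTR spread 15 of 1000 simulated unchanged groups moved the stress list as far. With the spread of all libraries 0 of 1000 did, and the wound-edge list was not simulated. An effect on JUN protein or translation without a fall in mRNA may remain, and was not tested. For both Mi2KD (4617 genes) and JUNKD (1911 genes) 1 of 10 splits of the 6 libraries, the real one, called as many genes, and the highest other split called 0; with 10 splits a share under 0.05 cannot be reached.

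Genes lower in Mi2KD were over-represented among genes higher at 6 h in the mouse. Expression level as the cause is argued against by a common odds ratio of 2.6 (95% interval 2.29 to 2.94) within 10 bins of expression, beside 2.53 without bins. The interval takes genes as independent units and does not measure the spread between libraries. For the overlap at 6 h, cell cycle genes are argued against as the cause, since 1 of 28 was called higher then. The overlap at 24 h, when cell cycle genes rose, is not covered by this test. A shared regulation by Mi-2β and barrier disruption may remain as a hypothesis, as may a difference between cultured and tissue keratinocytes, which the design does not separate.

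Few genes were called between DKD and Mi2KD. JUN mRNA did not pass between them either (log2 change -0.40, limma adjusted p = 0.59), and that the groups truly differ little is not excluded. The 2 DKD libraries may limit the calls: in simulated data 9 of 100 genes changed 2-fold were recovered in this comparison, and 82 of 100 changed 4-fold. Replicates of different kinds in the 2 groups may also limit the calls, but the block test cannot decide this. Numbering the DKD libraries as the file header does and using the number as a block called 589 genes (353 higher and 236 lower). A block with the labels' numbers, which did not pair DKD with the other groups, called still more. A rise in the count therefore does not mark matched replicates. The header numbering is a hint and not a label: by it 6 of 6 correlations of deviations with the other groups were over 0.1, against 3 of 6 by the labels' numbers, but with 2 libraries the pairing remains open. DKD against CTR, with the same 2 libraries, called 3273 genes.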

How the results depend on the processing

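The edgeR, TMM scaling, renumbered block and left-out library tests (the 4 libraries lowest on the third principal component of experiment 2; 2 mouse libraries rich in Cd34 and Tyrp1) were chosen after the data were seen, as were the agreement alternatives. Over values other than the main comparisons, 3743 kept their direction and side of the threshold, 431 became weaker, 52 became stronger and 0 reversed, fry's answers to its own question included. Over the main comparisons 160 stayed within their limits, 88 moved, 7 became weaker, 1 became stronger and 2 were counted as reversed. Of these the odds ratio of genes lower at 24 h started from 1.0, which has no direction, so it is not a true reversal. The cause was not tested, unless fewer genes or libraries account for it. Pseudocounts of 0.5 and 5 and a strict count filter kept 11 of 11 counts within 1.5 times. Leaving out the 2 mouse libraries gave 4969 genes at 6 h, 2311 at 24 h and 2026 between them, with 1 WT and 1 24 h library assumed to vary like the 6 h pair. The mouse comparison at 96 h was not run. A value cannot resolve less than 1 read. Simulated 2-fold changes were recovered in 9 to 64 of 100 cases, and in 2 of 100 in the interaction; depth was not varied in the simulations.

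Requiring at least 2-fold left 3338 genes at 6 h, 1071 at 24 h, 1357 between them, 3169 at day 3, 4978 at day 5, 2759 in Mi2KD, 1067 in JUNKD, and 2181 shared by the experiments (3773 without). Day 5 against day 3 (30 genes) gave 999 with DESeq2, 125 with edgeR and RLE size factors, 130 with edgeR and TMM, 130 with TMM scaling, 1 with no filter and 0 with only the compared groups. DKD against Mi2KD (17 genes) gave 555 with DESeq2, 31 with TMM scaling and 0 with only the compared groups. The interaction gave 61 with DESeq2. Only the compared groups gave 2484 in Mi2KD, 803 in JUNKD and 1277 in DKD. Without the 4 libraries lowest on the third principal component, 0 genes were called in JUNKD, 454 in DKD and 0 between DKD and Mi2KD by limma.

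With the replicate block 3995 genes were called at 24 h, 594 between day 5 and day 3, 3892 in JUNKD and 1236 between DKD and Mi2KD. With the DKD libraries renumbered, the block gave 7803 in Mi2KD, 5316 in JUNKD, 6434 in DKD and 589 between DKD and Mi2KD. Of 6 correlations of DKD with the other groups, 3 were over 0.1 and 3 under -0.1 by the labels' numbers, which do not pair, and 6 were over 0.1 by the file header's. The deviations of 2 libraries mirror each other, so these 6 are not independent, and 2 pairs do not establish a pairing. Libraries with the same number correlated at 0.263, 0.419 and 0.374 between the mouse groups and at 0.276, 0.143 and 0.367 between those of experiment 1, but 2 libraries per group do not establish pairs. The block with the labels' numbers changed no Mi2KD or JUNKD list call or named gene call; with the renumbering CHD4 passed in JUNKD (adjusted p = 0.0251; 0.0251 to 0.499 over the alternatives).

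Leaving out single libraries, where a group of 2 keeps 1 library that is assumed to vary like the other groups, gave 3800 to 5486 genes at 6 h, 421 to 1957 at 24 h, 855 to 1719 between them, 2194 to 3078 at day 3, 4818 to 7429 at day 5, 0 to 487 between day 5 and day 3, 2491 to 4652 in Mi2KD, 171 to 1860 in JUNKD, 395 to 3578 in DKD, 0 to 4 between DKD and Mi2KD and 0 to 1 in the interaction.

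Of 83 list calls with the preset correlation, 5 held with an estimated correlation. fry, which tests a list against no change and not against other genes, made 45 calls. The risen and fallen sets of experiment 1 between DKD and Mi2KD had p = 0.216 and 0.259 with an estimated correlation, and fry gave 0.301 and 0.138 in its own test. With the spread of all libraries of experiment 2 in place of CTR, simulated unchanged groups gave DKD medians of -0.56 to 0.6 for the stress list, -0.27 to 0.27 for the risen set and -0.32 to 0.3 for the fallen set.

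A −log10 q of at least 10 left 7037 Chd4-/- regions, 1227 at 6 h, 578 at 24 h, and in reverse 343, 2 and 3. The overlap of 6 h regions with Chd4-/- regions became 23.06%, of 24 h regions 31.14%, and of 24 h with 6 h regions 47.06%; with 50% reciprocal overlap they were 20.9, 22.87 and 37.5%. With a window of 10 kb and the nearest genes kept, the odds ratio of genes lower at 6 h was 0.955 (0.856 with 50 kb). That of genes lower at 24 h was 1.31 with 10 kb and 0.877 with 100 kb, from 1.0 with 50 kb, which has no direction.

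The HaCaT list gave an odds ratio of 0.9 for genes higher in Mi2KD, reversed from 1.14, and 1.08 for lower genes, from 1.5. List 1 alone gave 6.45% of cJUN peaks of Mi2KD in Mi-2β peaks (4.35% in both lists), 65.16% of Mi-2β peaks in H3K27ac (75.53%) and an odds ratio of 1.07 for higher genes; list 2 alone gave 19.68% and 51.78%. With 50% of the shorter peak the shares were 3.56% of cJUN in Mi-2β, 68.21% of Mi-2β in H3K27ac and 52.68% of H3K27ac of Mi2KD in CTR (54.76%). With the stronger 50% of peaks they were 3.37, 66.86 and 61.48%, and cJUN in JUNB was 23.26% (27.4%).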

Other observations

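The TMM scaling values and the principal component values were chosen only after the results were seen.

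The remaining fixed lists add to the account of the skin response. Immediate early and MAPK feedback genes rose in 11 of 20 at 6 h and fell in 1, or 11 and 2 adjusted over the list alone (adjusted p = 0.000345; adjusted p = 0.534 with an estimated correlation), and spinous layer genes rose in 8 of 17 and fell in 3 (adjusted p = 0.0271; adjusted p = 0.744 with an estimated correlation). p53 targets and cell cycle inhibitors rose in 4 of 15 and fell in 6 (adjusted p = 0.65), NuRD subunits fell in 3 of 13 (adjusted p = 0.787), interferon genes fell in 2 of 17, or 0 adjusted over the list alone (adjusted p = 0.864; median -0.14, against an upward direction of the test) and mesenchymal transition genes in 3 of 5 (adjusted p = 0.335). Cholesterol genes rose in 8 of 17 at 6 h, or 7 adjusted over the list alone (adjusted p = 0.00762; adjusted p = 0.636 with an estimated correlation). Unfolded protein and amino acid stress genes rose in 5 of 11 and fell in 2 (adjusted p = 0.0135; adjusted p = 0.534 with an estimated correlation). Hair follicle and sebaceous markers fell in 3 of 8 and Langerhans markers in 2 of 3 (adjusted p = 0.335 each), while leukocyte markers did not pass, in 2 tested. In the libraries labelled JUNKD, hair follicle markers rose in 1 of 6, or rose in 1 and fell in 3 adjusted over the list alone (median -0.81, adjusted p = 0.0236; adjusted p = 0.237 with an estimated correlation).

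In Mi2KD of experiment 2, spinous genes rose in 2 and fell in 2, basal layer genes rose in 1 and fell in 1, p53 targets rose in 3 and fell in 4, NuRD subunits rose in 1 and fell in 2, and mesenchymal genes gave 0 calls by limma. None of these lists passed. In the cell types, leukocyte markers rose in 1 of 2, neutrophil and endothelial markers in 1 each, hair follicle markers rose in 2 of 6 and fell in 1, and melanocyte markers gave 0 calls in 6. The antimicrobial list fell in 3 of 13 and rose in 1, or 7 and 1 adjusted over the list alone (adjusted p = 0.0311; 0.0661 with TMM scaling), the immediate early list fell in 4 of 22 (adjusted p = 0.0452; 0.0591 with TMM scaling), and the barrier lipid list rose in 2 of 15 and fell in 6, or 2 and 7 adjusted over the list alone (adjusted p = 0.0495; 0.0943 with TMM scaling). With an estimated correlation these 3 had adjusted p = 0.645, 0.577 and 0.577, and over the alternatives 0.0136 to 0.645, 0.039 to 0.577 and 0.039 to 0.577.

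In experiment 2 the third CTR, Mi2KD and JUNKD libraries and the second DKD library had the lowest values of the third principal component, which held 18.5% of the variance: -28.62, -13.82, -45.89 and -58.4, with the other libraries between -6.09 and 46.06.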
